A study of Homo sapiens with 6 samples.

How the data were processed

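GUIDE-seq maps where a nuclease breaks DNA in living cells: a short double-stranded DNA tag is captured in the break, and the tagged places are amplified and sequenced. Per the labels' protocols, HEK293 cells (a human embryonic kidney cell line) that stably express the Cas9 nuclease were nucleofected with a guide RNA complex and the tag. Genomic DNA was fragmented, ligated to adapters, amplified in successive rounds and read as paired reads of 150 bases on a MiSeq. The 6 samples are 6 guides named SG1, SG2, SG3, SG4, SG7 and SG8, each with 1 library, and all aimed at PKLR. No replicate, untreated library or tag-only library was analysed here.

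Each library has 1 deposited list of genomic sites. The deposited count of a site is a whole number, not normalized, and it ranges upward from 2 in 5 libraries and from 3 in SG8. The column name given per the file headers belongs to GUIDE-seq site callers and stands there for a sum over both strands. Whether it counts reads or consolidated molecules is not given in the sources used here, so the values are called counts. The authors also deposited a ratio per site. It equals the site's count over that of the PKLR site in 5 lists, and over that of the most counted site in the SG4 list. This was tested on every listed site, and the largest difference was 4.99e-10 in the SG2 list. To put all guides on 1 scale, the percentages below were recomputed from the counts with the PKLR count as 100%. The submitters' processing notes name the genome build hg38. The aligner, the site caller and its filters are not given in the sources used here. Positions are printed as the lists give them, and whether they count from 0 or 1 is not stated.

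The on-target site of a library was the most counted listed site inside PKLR, and every other listed site was taken as an off-target site. The choice by fewest mismatches, fixed before, could not be made, because the lists hold no sequences. Sites were placed in genes with a RefSeq gene table of the same genome (GRCh38, patch release 14), by whether the position lay between a gene's start and end. The table holds no exons, so exon, intron and UTR are not distinguished. A site in 2 overlapping genes is named with both, and protein-coding genes were named before others. The share of sites inside genes was set beside the percent of sequence that protein-coding genes cover between the first and last annotated gene of chromosomes 1 to 22 and X.

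With 1 library per guide no test between guides was made. Shares have exact Clopper-Pearson 95% intervals, and ratios of 2 counts have intervals from the same method. Amplified reads are not independent molecules, so these intervals cover counting error only. The lists hold only sites above a minimum, so no share or ratio was bounded for a site that is not listed. Only the models of carry-over between libraries assumed that such a site had fewer than 2 counts. Total listed counts ran from 4079 (SG7) to 79227 (SG4), a 19.4-fold range, and PKLR counts from 2728 (SG1) to 7549 (SG8), a 2.77-fold range. The total of a list holds the off-target counts and is not the sequencing depth. Sites of 2 libraries were called shared when they overlapped after each was widened by 50 bp, with PKLR on-target sites left out.

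The rule for naming sites and 2 gene lists were fixed before the data were examined. Named are each guide's on-target site, its 5 most counted off-target sites, every off-target site inside a gene of the lists, and the 5 most counted sites shared between guides. The lists hold 117 cancer genes and 62 genes, besides PKLR, of red cells, blood formation and glycolysis, and all of them were found in the gene table. Some sites that the rule would name are not reported here. Parts of the rule that needed mismatches or coding exons could not be applied. The number of sites in list genes was tested against the lists' share of protein-coding sequence (exact binomial test, two-sided, Benjamini-Hochberg over 12 tests), a test added after the lists of sites were seen. Planned analyses of mismatch numbers, mismatch positions, PAMs, and the share of matching genomic sites were not made, since they need guide sequences and a genome.

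Alternatives were minimum counts, thinning to a common depth (1000 random draws, keeping sites with 2 or more counts), merging sites within 100 bp, leaving out shared sites, other overlap windows and all annotated genes. The code for matching, thinning and gene look-up was run on simulated data. All 107 planted shared sites were recovered with 0 unplanted matches, and all 300 gene midpoints returned their gene. A midpoint lies between a gene's start and end by definition, so the look-up result could only reveal coding errors. Likewise, the planted sites check the code and do not estimate missed or false matches in the deposited lists. Thinned numbers of sites lay within 0.613% of the exact expectation. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.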

Results

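GUIDE-seq sites were compared for 6 guide RNAs aimed at PKLR, the gene of the pyruvate kinase of liver and red blood cells, in HEK293 cells that stably express Cas9. The study asked where else in the genome each guide led to tagged breaks. The 6 libraries listed 1626 sites in all, of which 1620 were off-target. Total listed counts were 32750 for SG1, 76822 for SG2, 13718 for SG3, 79227 for SG4, 4079 for SG7 and 10337 for SG8. Each guide had 1 library, so none of the differences between guides below has a replicate check, and no test between guides was made.

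All 6 guides had a listed site inside PKLR (chromosome 1, 155289293 to 155308654, hg38), and these 6 positions lay within 117 bp of each other. SG7 was listed at position 155301389 with 4030 counts and SG1 at 155301433 with 2728 counts. SG3 was listed at 155301467 with 3087 counts, and SG8 1 bp further at 155301468 with 7549 counts. SG4 was listed at 155301503 with 4654 counts, and SG2 3 bp further at 155301506 with 5335 counts. PKLR was the most counted site for SG1, SG3, SG7 and SG8, the second for SG2 and the third for SG4.

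**Figure D1:**
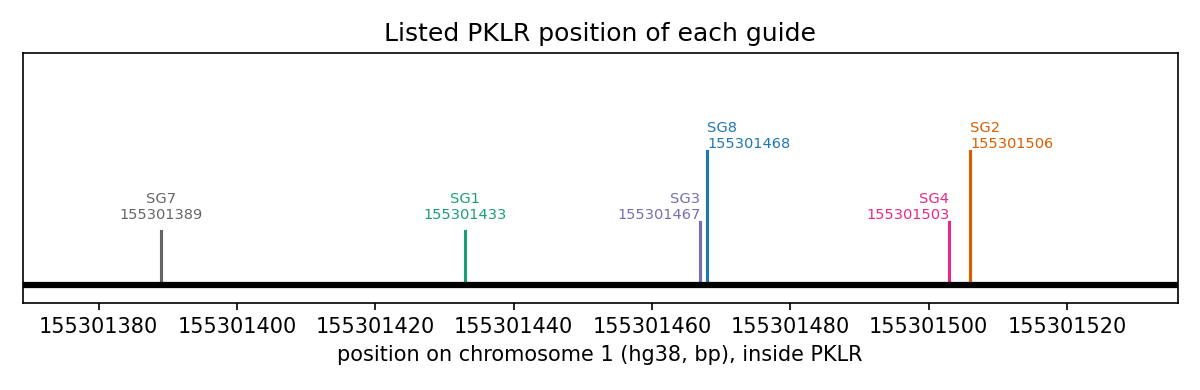
Position on chromosome 1 (hg38, bp) of the site inside PKLR listed for each guide, 1 line per guide; line height has no meaning and only separates the labels. The 6 positions run from 155301389 (SG7) to 155301506 (SG2), with SG3 and SG8 1 bp apart and SG4 and SG2 3 bp apart.

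The share of listed counts at PKLR was highest for SG7 and lowest for SG4. It was 98.8% for SG7 (exact 95% interval 98.4 to 99.1%) and 73.0% for SG8 (72.2 to 73.9%). SG3 had 22.5% (21.8 to 23.2%). The other guides lay under 10%: SG1 had 8.33% (8.03 to 8.63%), SG2 had 6.94% (6.77 to 7.13%) and SG4 had 5.87% (5.71 to 6.04%). The intervals of the 6 libraries did not overlap, but they cover counting error only and not the spread between repeated nucleofections. Summed off-target counts were 16.0 times the PKLR count for SG4, 13.4 times for SG2, 11.0 times for SG1 and 3.44 times for SG3. They were 0.369 times the PKLR count for SG8 and 0.0122 times for SG7.

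The number of off-target sites followed the same division. SG4 had 554, SG2 had 534 and SG1 had 448, against 49 for SG3, 28 for SG8 and 7 for SG7. Sites with at least 1% of the guide's PKLR count numbered 161 for SG4, 147 for SG1, 142 for SG2, 25 for SG3, 9 for SG8 and 0 for SG7. Sites with at least 10% of it numbered 28 for SG4, 28 for SG2, 22 for SG1, 9 for SG3, 1 for SG8 and 0 for SG7. Of all listed counts, 50% lay in 16 sites for SG1, 13 for SG4, 12 for SG2 and 4 for SG3, and in the PKLR site alone for SG7 and SG8. Thinned to the total of the SG7 list, the libraries kept a mean of 252.5 (SG1), 216 (SG4), 209 (SG2), 43.7 (SG3), 25.1 (SG8) and 7 (SG7) off-target sites.

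**Figure D2:**
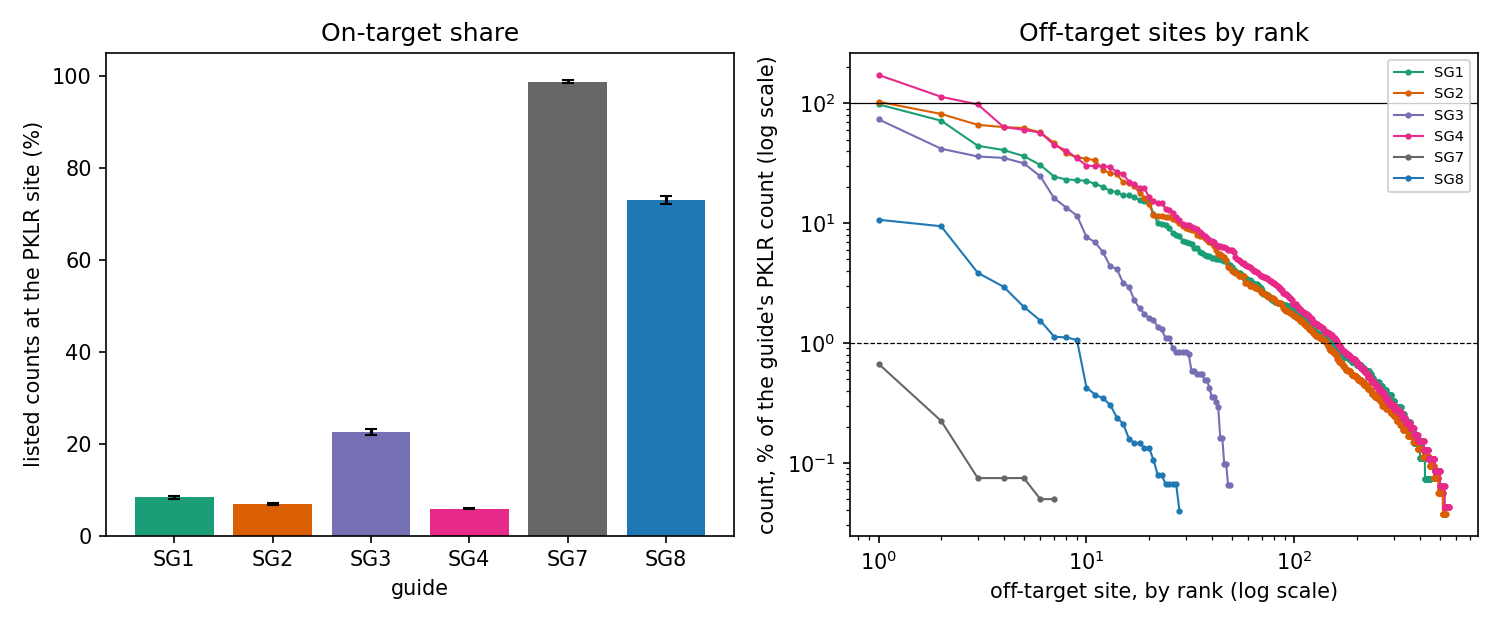
Left, percent of each library's listed counts at the PKLR site, with exact 95% intervals that cover counting error only (1 library per guide). Right, count of each off-target site as a percent of the guide's PKLR count against its rank, both axes logarithmic, with a solid line at 100% and a dashed line at 1%. The curves of SG1, SG2 and SG4 cross the 1% line at 147, 142 and 161 sites, while SG7 stays below it.

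The most counted off-target site of SG4, at position 237903006 of chromosome 1 inside the transcribed pseudogene LOC100130331, had 8052 counts, or 173% of the PKLR count (167 to 179%). A site in CCDC57 (chromosome 17, 82203780) had 4569 counts, and its interval of 94.2 to 102% of the PKLR count includes 100%. Other leading sites were outside genes (chromosome 2, 131832137, 2954 counts, 63.5%) and in FXYD7, a regulator of the sodium pump (chromosome 19, 35145435, 2805 counts, 60.3%). SG4 also had 2 further listed positions inside PKLR, with 13 counts at 155301550 and 7 counts at 155300916. The authors' deposited ratios for SG4 are relative to the site in LOC100130331, so PKLR stands there at 0.578.

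For SG2, a site in GUCY2F (chromosome X, 109468691), which encodes a guanylate cyclase of the retina, had 5515 counts against 5335 at PKLR. That is 103% of the PKLR count, with an interval of 99.5 to 107%, so counting error does not separate them. Sites in MYO18A (chromosome 17, 29118022, 4359 counts), outside genes (chromosome 15, 40349348, 3536 counts), in the forkhead gene FOXN3 (chromosome 14, 89294181, 3384 counts) and in the myosin gene MYO5B (chromosome 18, 49840992, 3327 counts) followed at 81.7%, 66.3%, 63.4% and 62.4% of the PKLR count. For SG1, a site in SYNJ2, a phosphoinositide phosphatase (chromosome 6, 158089526), had 2680 counts, or 98.2% of the PKLR count (93.1 to 104%). A site in the overlapping genes CIB1 and TTLL13 (chromosome 15, 90250661) had 1959 counts (71.8%). A site at the outermost annotated base of ETHE1 (chromosome 19, 43527201), a mitochondrial sulfur dioxygenase, had 1209 counts (44.3%). The other leading SG1 sites were outside genes, at 27361164 on chromosome 13 (1113 counts, 40.8%) and 85060973 on chromosome 10 (990 counts, 36.3%).

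The leading off-target site of SG3 lay in ARID4A, a chromatin gene (chromosome 14, 58312554, 2273 counts), at 73.6% of the PKLR count (69.7 to 77.8%). Sites in VDAC1, the mitochondrial outer membrane channel (chromosome 5, 134063729, 1293 counts, 41.9%), SMCHD1, a gene of X inactivation (chromosome 18, 2710814, 1114 counts, 36.1%), and PRRG1 (chromosome X, 37455875, 1083 counts, 35.1%) followed. The fifth was outside genes on chromosome X (68453025, 976 counts, 31.6%). For SG8 the leading sites were weaker: RBMS3, an RNA-binding protein gene (chromosome 3, 29669970, 807 counts), had 10.7% of the PKLR count (9.93 to 11.5%), and ERBB4, a receptor tyrosine kinase gene (chromosome 2, 212497988, 712 counts), had 9.43% (8.72 to 10.2%). Sites in the long non-coding RNA genes CSRP3-AS1 (chromosome 11, 19284971, 291 counts) and LOC105370777 (chromosome 15, 39180928, 151 counts) had 3.85% and 2.00%, and 1 site outside genes (chromosome 11, 14369864, 222 counts) had 2.94%. For SG7 the leading site lay in TNF, the gene of tumour necrosis factor (chromosome 6, 31575761). It had 27 counts, or 0.670% of the PKLR count (0.441 to 0.976%). The next had 9 counts (chromosome X, 137191043, outside genes), and the other 5 had 2 or 3 counts, with ERBB4 at 3 counts among them. That ERBB4 site lay at the position of the SG8 site (212497988), where SG8 had 712 counts.

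Of the 2 gene lists, the cancer genes held 12 off-target sites over all 6 guides, against 12.6 that their share of protein-coding sequence would give. The red cell, blood-forming and glycolysis genes held 2, against 2.72. No guide's number of sites in either list passed adjustment (exact binomial test, two-sided, 12 tests). The lowest raw p was 0.0442 and the lowest adjusted p 0.531, for SG7 and the cancer genes with 1 site in ERBB4. The comparison assumes that sites could fall evenly over protein-coding genes. It also counts 1 place in ERBB4 (212497988) for 3 guides, with 712 counts in SG8, 3 in SG7 and 3 in SG1. Carry-over between libraries stays open for such low counts, as given under the third pattern below. Most sites in list genes had few counts. The exceptions were ERBB4 for SG8, given above, and RUNX1 for SG4, a transcription factor gene of blood formation on both lists, where position 34862656 of chromosome 21 had 189 counts, or 4.06% of the PKLR count (3.49 to 4.70%). SG2 had 41 counts in CDK6, a cell cycle kinase (0.769%), 21 in FBXW7, a ubiquitin ligase subunit, and 3 in the mismatch repair gene MSH6. SG1 had 13 counts in WWOX, 9 in ALK, 8 in LRP1B, and 8 and 3 at different positions in ERBB4, each under 0.5% of the PKLR count. SG4 had 5 counts in ERG, a further transcription factor gene of blood formation. SG3 had no off-target site in a list gene.

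Protein-coding genes held 54.2% of the off-target sites of SG1 (exact 95% interval 49.5 to 58.9%, 448 sites), 53.5% of those of SG2 (49.1 to 57.8%, 533 sites) and 49.7% of those of SG4 (45.5 to 54.0%, 553 sites). These intervals lay above the 41.6% of sequence that protein-coding genes cover. The shares were 46.9% for SG3 (32.5 to 61.7%), 57.1% for SG8 (37.2 to 75.5%) and 42.9% for SG7 (9.90 to 81.6%), and their intervals include 41.6%. Among sites with at least 1% of the PKLR count the share was 46.9% for SG1 (38.7 to 55.3%) and 48.6% for SG2 (40.1 to 57.1%), which include 41.6%, and 55.0% for SG4 (46.9 to 62.9%), which does not. Even placement is a rough background, since guide matches are not spread evenly over the genome. The 41.6% also counts all sequence between the first and last annotated gene, whether or not a site could be listed there.

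SG3 and SG8, with PKLR positions 1 bp apart, listed 11 off-target sites in common, which were 22.4% of the SG3 sites and 39.3% of the SG8 sites. They held 40.4% of the off-target counts of SG3 and 46.9% of those of SG8. Relative to PKLR, 9 of the 11 were higher for SG3: VDAC1 had 41.9% against 0.305% for SG8, and SMCHD1 36.1% against 0.0662%. RBMS3 went the other way, with 0.0648% for SG3 and 10.7% for SG8, as did FOXC1, a forkhead gene, with 0.810% and 1.11%. A site outside genes on chromosome 11 had 13.5% for SG3 and 2.94% for SG8. LRP6, a Wnt co-receptor, had 28 counts for SG3 and 26 for SG8, and CDKAL1 had 498 and 12. FOXC1, LRP6 and CDKAL1 lie outside the naming rule and were chosen after their values were seen. The relation of log10 counts across the 11 sites was not distinguishable from none (Pearson's r = -0.45, two-sided permutation p = 0.177 with 100000 draws; Spearman's rho = -0.31, permutation p = 0.342). Without the 2 sites farthest from the SG3 median, r was -0.05 (exact permutation p = 0.909) and rho -0.06 (exact permutation p = 0.886). Sites within a pair of libraries are not replicates, and this pair was chosen after the lists were seen.

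**Figure D3:**
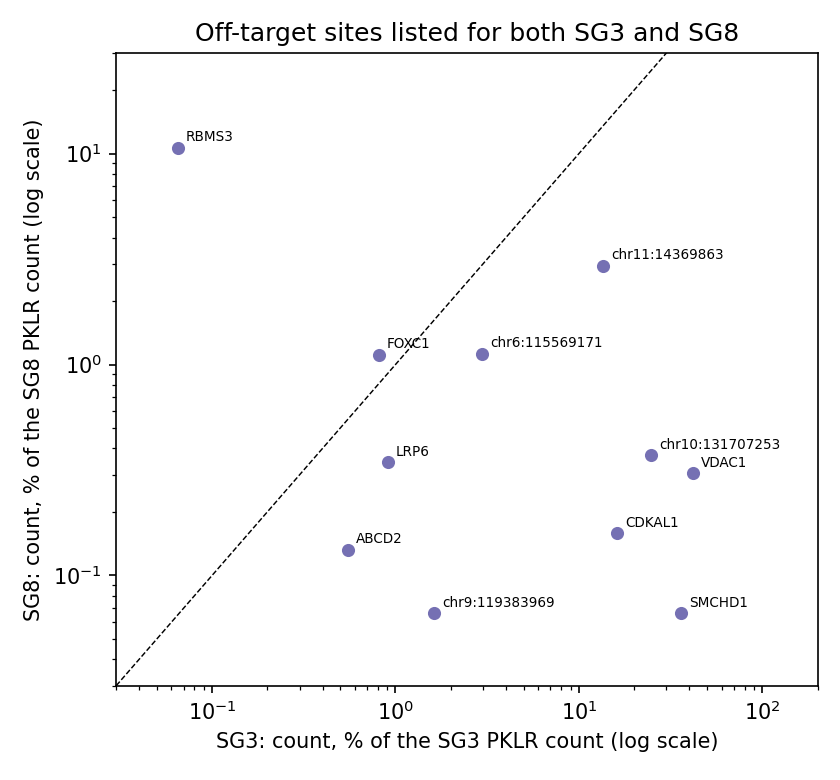
Each point is 1 of the 11 off-target sites listed for both SG3 and SG8, with its count as a percent of the guide's own PKLR count, both axes logarithmic; the dashed line marks equal percentages. The 9 points right of the line are relatively higher for SG3, with VDAC1 at 41.9% against 0.305%, and RBMS3 and FOXC1 lie left of it.

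SG2 and SG4, with PKLR positions 3 bp apart, listed only 4 common off-target sites among 534 and 554. In all, 21 places were listed for more than 1 guide, 15 of them in 2 libraries and 6 in 3 libraries. Of the 15 pairs of guides, 5 shared none, and pairs other than SG3 and SG8 shared at most 5, where random placement would give at most 0.0196 for any pair. The most counted shared places named here had high counts in 1 library and 10 or fewer in the others. GUCY2F had 5515 counts for SG2 and 3 for SG4. The site at 40349348 on chromosome 15 had 3536 for SG2 and 10 for SG1. FXYD7 had 2805 for SG4, 6 for SG1 and 3 for SG2. SYNJ2 had 2680 for SG1, 5 for SG3 and 5 for SG4.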

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

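Listed sites outside chromosomes 1 to 22 and X were left out of the gene comparisons. There were 2. SG2 had 16 counts at position 11224 of the mitochondrial genome, or 0.300% of its PKLR count. SG4 had 59 counts at position 12417 of the unplaced contig KI270438v1, or 1.27% of its PKLR count. No control library was analysed here to set them against.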

How the results depend on the processing

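Of 140 values recomputed under alternatives, 104 stayed within their counting interval or within 1.5 times for numbers of sites, 36 moved, and the order of the guides by PKLR share stayed as reported under each minimum count and each thinning. Thinning to the smallest PKLR count and leaving out sites with over 10 times the count in another library were chosen after seeing the data, and neither moved a value. With at least 10 counts per site, off-target sites numbered 293 for SG1, 351 for SG2, 360 for SG4 and 1 for SG7, whose PKLR share was 99.3%. With at least 1% of the PKLR count they numbered 147, 142, 25, 161, 0 and 9 for SG1, SG2, SG3, SG4, SG7 and SG8. PKLR shares were then 9.23% (SG1), 7.49% (SG2), 6.29% (SG4), 100% (SG7) and 74.8% (SG8), and the share of sites in protein-coding genes was 46.9% (SG1), 48.6% (SG2) and 55.0% (SG4). Thinned to the smallest total, SG1, SG2 and SG4 had 252.5, 209 and 216 off-target sites, and SG2 had a PKLR share of 7.17%. Without sites listed for more than 1 guide, PKLR shares were 9.29% (SG1), 7.87% (SG2), 32.8% (SG3), 6.70% (SG4) and 90.8% (SG8). The top off-target site then had 71.8% (SG1), 81.7% (SG2) and 3.85% (SG8) of the PKLR count, and SG8 had 16 off-target sites; fewer sites enter by construction. Counting all annotated genes gave 63.4% (SG1), 64.7% (SG2) and 63.5% (SG4) of sites inside genes, where these genes cover 55.2% of sequence. Requiring the same base gave 7 sites shared by SG3 and SG8 in place of 11. Merging neighbouring sites moved nothing beyond these limits. No paired analysis was possible because each guide has 1 library, and no library could be left out for the same reason. With at least 1% of the PKLR count, SG7 kept no off-target site and so gave no top ratio or gene share. Recomputations with a mismatch limit, NGG PAMs, counts against mismatches, the PAM-proximal share, the share of matching genomic sites and both drawn backgrounds for the gene share were not run, since the lists hold positions without sequences and no genome sequence was used. Intervals cover counting error only, and sites with 2 or 3 counts carry little weight on their own.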

Other observations

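Only the test of depth by thinning to the smallest total was set before its result was seen; all other tests here were chosen after the values were seen. Apart from the shared places, 40 protein-coding genes held off-target sites of more than 1 guide at different positions. Placing each guide's sites over protein-coding genes by gene length gave a mean of 44.1 such genes (95% of 1000 draws between 32 and 56), so the overlap of genes was no larger than length gives. The hit genes were long, with a median of 243942 bp against 24170.5 bp for all. TBC1D22A, IL16 and PEBP4, named after their values were seen, held sites of 3 guides, where 2.54 such genes were expected. In SG1 the sites under 1% of the PKLR count lay in protein-coding genes more often than those above it (57.8% against 46.9%, Fisher's exact test, two-sided p = 0.0340), but the difference did not pass adjustment over 3 libraries (adjusted p = 0.102). It was 55.2% against 48.6% in SG2 and 47.6% against 55.0% in SG4. SG2 and SG4 listed 3 and 6 pairs of sites within 100 bp of each other and the other libraries none, among them 2805 and 26 counts 40 bp apart in FXYD7 and 2097 and 8 counts 52 bp apart in SLC23A1.

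The first pattern is the range of 7 to 554 off-target sites, 79.1-fold. Depth, as far as listed counts show it, does not account for it: with every library thinned to the smallest total the range was still 36.1-fold, and with every library thinned to the smallest PKLR count it was 99.1-fold. PKLR counts differed by at most 2.77-fold between libraries. Listed counts are not the sequencing depth, so read depth and library complexity themselves were not tested and stay open. Also open and untested are the guide sequence and the variation between nucleofections. The design varies the guide sequence but the lists do not give it, and 1 library per guide cannot show the variation between nucleofections.

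The second pattern is the set of 11 sites common to SG3 and SG8. Carry-over in proportion to the counts, with 1 rate per direction fitted on all off-target sites of both libraries, does not account for the set (simulated p of the fit 0.001, the smallest that 1000 draws can give). The fitted rate of 4.07% from SG3 would leave 92.6 counts of the ARID4A site in SG8, which did not list it, while the site on chromosome 6 at 115569171 had 91 counts in SG3 and 85 in SG8. Carry-over stays open for single sites of the set, such as RBMS3 with 2 counts in SG3 and 807 in SG8. A candidate explanation for the set is that the guides overlap in sequence. Of the 11 sites, 5 had counts under 10 times apart. SG2 and SG4, 3 bp apart, shared 4 sites, of which 0 had counts under 10 times apart. Without sequences and strands the explanation cannot be decided.

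The third pattern is 16 low counts, of 2 to 10, at 12 places that another guide's library lists at 80 to 5515 counts. The pair of SG3 and SG8 is left out of these numbers and of the tests below. Breaks that do not depend on the guide and fall evenly over the other guide's sites are argued against. With each place taken once, 10 of the 12 ranked within the top 12 of the other list. The geometric mean count of the places there was 1246 against 150 for sites drawn evenly from those with over 10 times the low count (one-sided permutation p = 0.0001, the smallest that 10000 draws can give). Guide-independent breaks that favour the most counted sites would give the same result, so the test cannot exclude them. Carry-over in proportion to the counts may account for the off-target sites (fitted rates of 0.0170 to 0.200% per pair of libraries, simulated p of the fit 0.101). With 10 rates fitted for 16 low counts, that fit is a weak check. At those rates 5.48 PKLR sites of other guides would have been listed in 8 pairs of libraries and 0 were (exact Poisson probability of none at the fitted rates, p = 9.69e-14). However, the rates were fitted only for pairs of libraries with a low count and were then taken as known. The highest, 0.200% from SG8 to SG1 and to SG7, rested on 1 low count each, as did several of the others. The probability leaves out this selection and the error of the rates, so it does not decide against carry-over. Separate sites 16 to 52 bp apart were listed in SG2 and SG4 but not in the other libraries. Whether the other libraries could list sites so close was not tested. In 1 of the 8 pairs SG2 or SG4 would receive molecules, and that pair gave an expected 0.612 sites (exact Poisson probability of none, p = 0.388). With so few expected, this pair could not show a lack of sites and decides nothing. Because of the selection and the error of the rates, carry-over stays open.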
